A study of Homo sapiens with 16 samples.

How the data were processed

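Tumours grown from U87, an established human glioblastoma cell line carrying a luciferase reporter, in the brains of nude mice were profiled by RNA sequencing. The mice had received exosomes of mesenchymal stromal cells (MSC, as the labels abbreviate the source) loaded with a siRNA against human MYC or with a scramble siRNA, and the tumours were taken when each mouse met the criteria for euthanasia. The 16 libraries fall into 4 groups by label: Myc1 (MYC siRNA 1, n = 3), Scr1 (scramble 1, n = 4), Myc2 (MYC siRNA 2, n = 5) and Scr2 (scramble 2, n = 4). Each library comes from its own mouse, per the labels' titles. For the first pair of groups, dosing began on day 28 and was repeated every other day with 1e9 exosomes in 100 µl by retro-orbital injection. RNA with an integrity number of at least 7.2 was sequenced on an Illumina NextSeq instrument, per the labels' protocols.

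Per the submitters' processing notes, the tools were bcl2fastq 2.20.0, STAR 2.6.0b and Picard, and the genome builds were hg19 and mm10. The notes do not say which step used which build, and the counting tool, the annotation and any separation of mouse from human reads are not given in the sources used here. The authors deposited 1 table for each experiment, with log2 values per human Ensembl gene. The log2 unit was read from the values themselves: the deposited values, taken back from log2, summed to between 995054 and 998392 in every sample, and sorted values of different samples in a table coincided except for ties, so they are log2 CPM (counts scaled to a common library size) that had been quantile-normalized within each table. The table of the first experiment held 17318 genes, that of the second 18168, with 16957 in both and 0 mouse gene identifiers in either. Because quantile normalization gives every sample the same distribution, a change in total RNA or in most genes at once cannot be seen in these values. The experiments were normalized separately, so levels were compared only within a table.

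Library sizes were not given. The lowest distinct values of a sample lay at the spacing of log2(count + 0.5), and the offset of steps 2 to 20 gave an estimated library size. The estimates ranged from 15.3 to 24.0 M reads in the first experiment apart from Scr1 replicate 3, at 3.36 M, and from 15.2 to 31.0 M in the second apart from Scr2 replicate 4, at 10.1 M. On simulated counts with the same sizes, quantile-normalized in the same way, the estimates were off by at most 5.18% over 17318 genes and 3.07% over 18168 genes. The spacing had its lowest slopes in Scr2 replicates 1 and 4 (0.908 and 0.876) against a slope of 1 for ideal steps. Its highest slopes were in Myc2 replicates 3 and 4 (1.19 and 1.15). The sizes of these libraries are less certain. Scr1 replicate 3 had 8.81% of its genes at its lowest value.

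Each comparison was fitted with limma 3.58.1 in R 4.3.3 (empirical Bayes with trend and robust settings) on the deposited log2 values. The plan made before the data were examined called for log2(value + 1). Since the deposited values were already log2 CPM, they were used directly, and log2(CPM + 0.1), which was planned, and log2(CPM + 1), which was added, were run as alternatives. Genes entered a fit if at least 1 CPM was reached in as many samples as the smaller group had: 3 samples for siRNA 1, 4 for siRNA 2 and 3 for the joint fit over the 4 groups. A threshold of 0.05 was applied to p-values adjusted by the Benjamini-Hochberg method. The joint fit gave the mean of the siRNA 1 and siRNA 2 effects and their difference. Single values, such as MYC, were also compared by exact two-sided permutation of the labels, with 35 arrangements for siRNA 1, 126 for siRNA 2 and 4410 for both. With these sizes the smallest p is 0.0286 for siRNA 1 and 0.00794 for siRNA 2. Limma and permutation p-values for 1 siRNA measure the spread between mice of that experiment. Those for the mean and the difference rest on the mice of both experiments.

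A set of 34 gene lists fixed before the data were examined covered glioblastoma cell states and subtypes, MYC targets, cell cycle, metabolism, hypoxia, stress, inflammation, matrix and host cell types. The lists were written from memory of published signatures, so their members may differ from the published versions. Lists with at least 3 measured members were tested with limma's camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry. Camera sets the members of a list against the other genes. At the preset correlation it allows little for members that vary together between mice, so its p is not a measure of the spread between mice. A list score is the mean log2 CPM of the measured members in a sample. The host lists for erythroid cells (1 measured member in each experiment) and, in siRNA 1, lymphocytes (2 measured members) were too small to test. Where a symbol had several identifiers, the most abundant stood for it. The genes named were taken by a rule fixed before the data were examined: MYC, the genes past the threshold with separated groups or, when too few passed, those with the smallest p up to 20, up to 4 members with the smallest p from each list, and a panel of 16 mesenchymal and proneural markers whatever their result.

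On simulated data with 100 genes changed 2-fold and 100 changed 4-fold, the fit recovered 15% of 2-fold and 78% of 4-fold changes for siRNA 1 (13933 genes), 35% and 78% for siRNA 2 (14208 genes), and 69% and 93% for the mean of both (14891 genes). For the difference between siRNAs (14891 genes) it recovered 4% and 49%. These shares describe the simulated data alone. They do not give the share of real changes that would be found in tumours whose genes vary together between mice. Transcript lengths and GC content came from GENCODE transcripts matched by Ensembl identifier. That reference is of another build than those named in the processing notes, so no coordinates are given. The alternatives tried were other filters, limma without trend, sample weights, other pseudocounts, a host marker covariate, gene lists without members that are also host markers, 1 fit over the 4 groups, each library left out in turn, a median-of-ratios shift of each sample, and leaving out Scr2 replicates 1 and 4 together. The shift, log2(CPM + 1), the joint removal and an exact permutation of list scores were chosen after seeing the data.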

Results

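The series holds 16 RNA sequencing libraries of U87 glioblastoma xenografts from the brains of nude mice, in 2 experiments. In the first, 3 tumours of mice given exosomes with MYC siRNA 1 (Myc1) were set against 4 given scramble siRNA 1 (Scr1). In the second, 5 tumours with MYC siRNA 2 (Myc2) were set against 4 with scramble siRNA 2 (Scr2). MYC encodes a transcription factor that drives growth and ribosome production. The series title names the transition between the proneural and mesenchymal transcriptional states of glioblastoma as its subject, and the comparisons below therefore give MYC, markers of these states and the other gene lists. Estimated library sizes ran from 3.36 M reads (Scr1 replicate 3) to 31.0 M (Myc2 replicate 3). Within an experiment, libraries correlated at r = 0.933 to 0.974 across genes in the first and r = 0.904 to 0.969 in the second. In the first experiment the first principal component held 31.3% of the variance, with Scr1 replicate 4 at -61.5 and the other 6 libraries between -29.5 and 44.7. In the second it held 43.8%, and Scr2 replicates 1 and 4 lay at -63.4 and -94.4 on it, while the other 7 libraries lay between 2.74 and 47.6.

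MYC itself, the siRNA target, did not move the same way in the 2 experiments. In Myc1 tumours MYC stood at 4.61 ± 0.71 log2 CPM (SD, n = 3) and in Scr1 tumours at 5.44 ± 1.02 (SD, n = 4), a log2 difference of -0.83 with a 95% interval of -2.06 to 0.40, which was within the spread between mice (exact permutation p = 0.314, limma adjusted p = 0.996). Myc1 tumours held 38.1, 26.5 and 14.3 CPM and Scr1 tumours 21.2, 30.2, 50.7 and 108 CPM, so the groups overlapped. In the libraries labelled Myc2, MYC was higher than in those labelled Scr2, at 5.75 ± 0.29 log2 CPM (SD, n = 5) against 5.18 ± 0.37 (SD, n = 4), a log2 difference of 0.57 with a 95% interval of 0.10 to 1.04 (exact permutation p = 0.0397, limma adjusted p = 0.370). Myc2 libraries held 42.3 to 72.1 CPM and Scr2 libraries 25.9 to 47.1 CPM. The target's direction in this experiment goes against the label, so the second experiment's groups are named as labelled throughout. The 2 effects differed by -1.40 on the log2 scale (exact permutation p = 0.0580 over 4410 arrangements), and their mean was -0.13 (p = 0.769 by the same permutation). Leaving out Scr1 replicate 4, the library with the most MYC, left a log2 difference of -0.39 in the first experiment. In the second, the log2 difference stayed between 0.41 (without Scr2 replicate 4) and 0.70 (without Scr2 replicate 3) with 1 library left out. The permutation p was then 0.0357 to 0.107, with fewer arrangements possible.

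**Figure D1:**
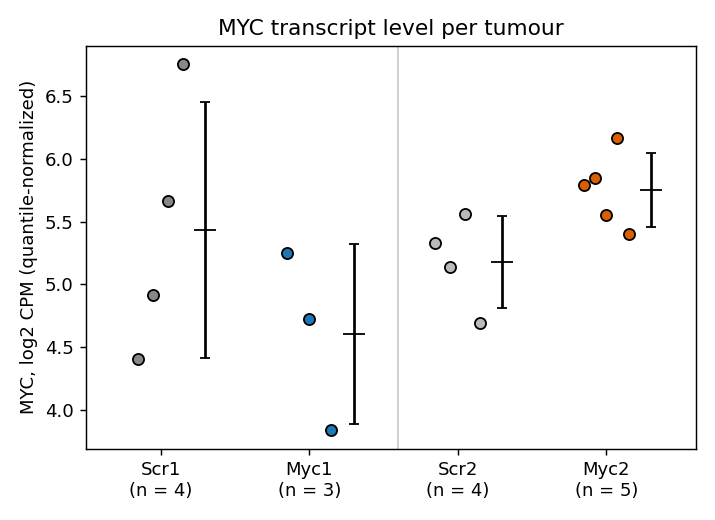
MYC level in each tumour, in log2 CPM, for the 4 groups. Points are single tumours, the bar beside them is the mean and its whiskers the SD; Myc1 and Scr1 overlap, and the libraries labelled Myc2 lie between 5.40 and 6.17 against 4.70 to 5.56 for Scr2.

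In the first experiment no gene passed the adjusted threshold, so the genes below are those with the smallest p and the list members, given as values. Complement genes and metallothioneins are named as single genes here and were not tested as groups of their own. C3, the central complement component, was 3.01 ± 0.56 (SE) log2 units higher in Myc1 than in Scr1, and the complement proteases C1S and C1R were higher by 1.53 ± 0.31 and 1.29 ± 0.26. CFB, complement factor B, was higher by 1.09 ± 0.27, AQP9, a water and glycerol channel, by 1.83 ± 0.27, and the lipid carrier APOE by 2.33 ± 0.57. The metal-binding MT1E and MT1F were higher by 1.40 ± 0.30 and 2.08 ± 0.54. IGFBP2 and IGFBP4, which bind insulin-like growth factors, differed by 1.83 ± 0.48 and 1.57 ± 0.39, and CHI3L2 by 1.18 ± 0.30. On the other side, FABP4, a fatty acid carrier, was at 0.69 ± 0.27 log2 CPM (SD, n = 3) in Myc1 and 2.17 ± 0.31 (SD, n = 4) in Scr1, and SH3BP1 differed by -1.39 ± 0.36. Limma called 0 of 13933 genes, with a smallest adjusted p of 0.0916 for AQP9. At an unadjusted p under 0.05 there were 485 genes, 273 higher and 212 lower, against 697 expected by chance. With 1 library left out this count ran from 181 (without Myc1 replicate 3) to 955 (without Scr1 replicate 3). Among all tested genes, 4.21% had groups that did not overlap, against 5.71% by chance.

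By gene list, 11 of 32 lists rose in Myc1 by camera and 0 fell, but 0 passed with an estimated correlation. Only the MES-like 1 and AC-like calls held whichever of the 7 libraries was left out. The MES-like 1 list, the mesenchymal-like state of single glioblastoma cells, rose (adjusted p = 2.97e-07, and adjusted p = 0.395 with an estimated correlation). Of its 47 measured members 34 lay above 0, 11 of them at an unadjusted p under 0.05, and 6 passed when adjusted over the list alone; C3, C1S, C1R and MT1E were among its members with the smallest p. The AC-like list, the astrocyte-like state, rose (adjusted p = 0.00114, and adjusted p = 0.395 with an estimated correlation), with 16 of 22 members above 0 and 3 past the threshold when adjusted over the list alone. Markers of astrocytes, a host cell type, rose as a list (9 measured members, median 0.53, adjusted p = 0.00260, and adjusted p = 0.524 with an estimated correlation), with the bicarbonate transporter SLC4A4 (2.15 ± 0.66) among the members past the threshold when adjusted over the list alone. Ribosomal protein genes rose by a median of 0.22 (64 of 68 members above 0, adjusted p = 2.97e-07) and oxidative phosphorylation genes by 0.17 (33 of 41, adjusted p = 0.00225). Both had an adjusted p of 0.777 with an estimated correlation. These rises depend on Scr1 replicate 4, whose ribosomal score was 8.68 against 9.23 to 9.52 in the other Scr1 tumours and 9.33 to 9.61 in Myc1, and whose oxidative phosphorylation score was 6.77 against 7.12 to 7.37 in the other Scr1 tumours. Without it both calls ended, at medians of 0.0436 (adjusted p = 0.166) and 0.0853 (adjusted p = 0.109), and the oxidative phosphorylation call also ended without Myc1 replicate 3. The hypoxic MES-like 2 list, where MT1X (1.48 ± 0.43) and NAMPT (0.98 ± 0.33) had small p, rose with adjusted p = 0.00225. The list of inflammatory and NF-kB targets, with ICAM1 (1.76 ± 0.66), NFKBIA (0.63 ± 0.26) and CXCL3 (1.27 ± 0.59), rose with adjusted p = 0.00426. These 2 lists had adjusted p = 0.524 and 0.777 with an estimated correlation, and both calls ended without Myc1 replicate 3, where the inflammatory median was 0.0280 instead of 0.58. The astrocyte and inflammatory calls ended without Scr1 replicate 1. Extracellular matrix (adjusted p = 0.0270), hypoxia core (adjusted p = 0.0359), angiogenic factor (adjusted p = 0.0400) and NPC-like (adjusted p = 0.0400) lists also rose. The first 3 of these had, with an estimated correlation, adjusted p = 0.777 and the NPC-like list adjusted p = 0.524. All 4 calls ended without Myc1 replicate 3, without Scr1 replicate 1 or without Scr1 replicate 3. The hypoxia median was 0.00383 without Myc1 replicate 3, and the matrix median -0.00808 without Scr1 replicate 1. The hypoxia and NPC-like calls also ended without Scr1 replicate 2, and the NPC-like call without Myc1 replicate 2.

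The lists closest to the study's subject did not pass in this experiment with all libraries. The mesenchymal subtype list had a median log2 difference of 0.06 (36 of 61 members above 0, adjusted p = 0.220), the proneural subtype list 0.10 (14 of 22, adjusted p = 0.408) and the mesenchymal regulators -0.01 (adjusted p = 0.922). Of the listed members, 22 of 41 were measured for the proneural subtype and 61 of 64 for the mesenchymal subtype. In the second experiment these were 22 of 41 and 62 of 64, so the proneural result rests on a smaller part of its list. Without Scr1 replicate 4 the mesenchymal subtype and regulators were called at camera's preset correlation (medians 0.08 and 0.15, each with adjusted p = 0.0411). The subtype list was also called without Scr1 replicate 3 (camera adjusted p = 0.0494), but its median was -0.00336 without Scr1 replicate 1. Among panel markers, CHI3L1, a secreted mesenchymal marker, was higher by 2.00 ± 0.69 log2 units (limma adjusted p = 0.996), and IL1R1 and LOX of the mesenchymal lists by 1.28 ± 0.35 and 0.79 ± 0.30. Without Myc1 replicate 3 the difference was 1.13 for CHI3L1, 0.52 for CXCL3, 0.41 for NFKBIA, 0.59 for MXI1 and 0.27 for PDGFRA. CD44 differed by -0.03 ± 0.23, VIM by 0.02 ± 0.18, FN1 by 0.06 ± 0.26, STAT3 by 0.05 ± 0.21, TIMP1 by 0.21 ± 0.22, MET by 0.24 ± 0.27 and CEBPB by 0.26 ± 0.22. Of the proneural markers, NCAM1 differed by 0.17 ± 0.30, PDGFRA by 0.75 ± 0.57 and BCAN by -0.40 ± 0.52, while SOX4 was higher by 1.26 ± 0.40. With 1 library left out MET ran from 0.0527 to 0.46, CEBPB from 0.15 to 0.47, NCAM1 from 0.0497 to 0.32 and BCAN from -0.84 to -0.16. OLIG2 stayed below the expression filter in both experiments, SOX2 was below it in the second, and SOX2 in the first and DLL3 in both were not analysed here. The MYC target list (Hallmark V2) had a median of -0.04 (adjusted p = 0.730) and the classic MYC-activated list -0.11 (adjusted p = 0.551); MXI1, a MYC antagonist, differed by 1.09 ± 0.39. The other host cell type lists tested, for neurons, oligodendrocytes, endothelium, microglia and pericytes, had adjusted p from 0.730 to 0.922. As a score per tumour, MES-like 1 was 7.62 ± 0.18 (SD, n = 3) in Myc1 and 7.14 ± 0.18 (SD, n = 4) in Scr1, with no overlap (exact permutation p = 0.0286, the smallest this design allows, and 0.457 after adjustment over the 32 lists). The number of lists called was 5 without Myc1 replicate 3 and 6 without Scr1 replicate 1, and the number of genes was 2 without Myc1 replicate 1, 2 without Myc1 replicate 2 and 1 without Scr1 replicate 2. Without the shallow Scr1 replicate 3, 10 lists passed, and the cell cycle lists were then lower (G2/M median -0.31, adjusted p = 5.77e-06, with camera's preset correlation). The G2/M median was -0.03 with all libraries (camera adjusted p = 0.922) and 0.20 without Scr1 replicate 1, so its sign depended on the library left out.

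**Figure D2:**
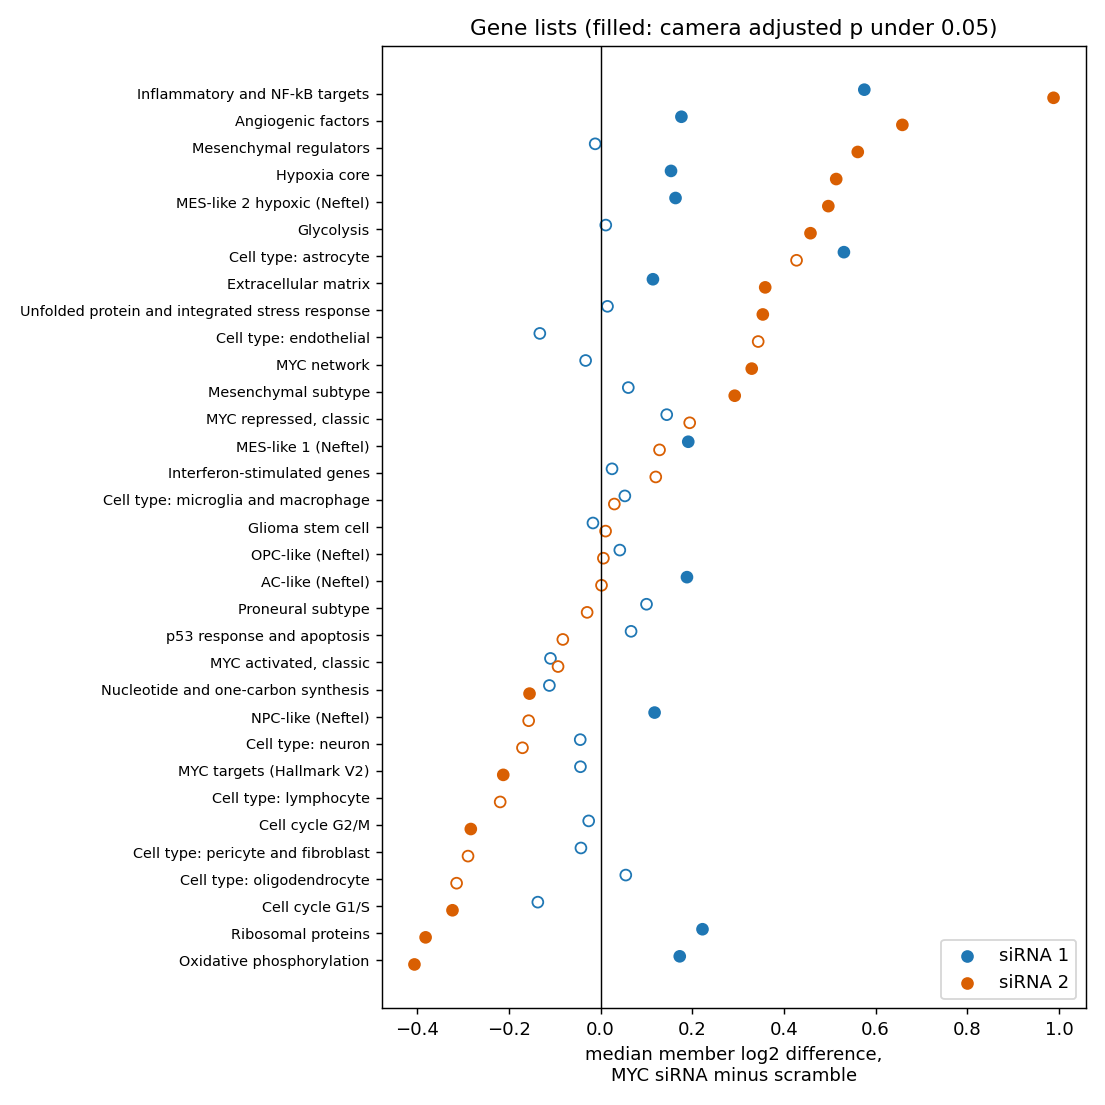
Median log2 difference (MYC siRNA minus scramble) of the measured members of each tested list, in both experiments. Filled points are lists with a camera adjusted p under 0.05 at the preset correlation; ribosomal protein genes lie at 0.22 in siRNA 1 and -0.38 in siRNA 2, and inflammatory targets at 0.58 and 0.99.

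In the second experiment 0 of 14208 genes passed the adjusted threshold, and 0 lists passed with an estimated correlation (smallest adjusted p = 0.241). At camera's preset correlation, lists of hypoxia, glucose use, NF-kB targets and the mesenchymal state were higher in the libraries labelled Myc2 and those of the cell cycle lower. Ribosomal and respiratory lists were also lower, but not without Scr2 replicates 1 and 4 (medians 0.06 and 0.0428). The genes with the smallest p are given as values. VEGFA, the hypoxia-induced angiogenic factor, stood at 10.34 ± 1.19 log2 CPM (SD, n = 5) in Myc2 and 7.54 ± 1.03 (SD, n = 4) in Scr2, a difference of 2.80 ± 0.61 (SE). CEBPB, a transcription factor that drives the mesenchymal state, was higher by 1.21 ± 0.22, CHI3L1 by 2.61 ± 0.54, the stress-induced mTOR inhibitor DDIT4 by 1.42 ± 0.29, BCL3, a regulator of NF-kB, by 1.27 ± 0.23, and OSMR, the oncostatin M receptor, by 1.01 ± 0.22. ERRFI1, a feedback inhibitor of EGFR, differed by 1.505 ± 0.33, SLC25A37 by 0.96 ± 0.20, WSB1 by 1.00 ± 0.22, STC2 by 3.95 ± 0.88 and EPPIN by 3.88 ± 0.66, the last 2 from means under 1 CPM in Scr2 (-0.64 and -1.98 log2 CPM). The lower genes with the smallest p were ATP5EP2 (-3.22 ± 0.56), PMS2P10 (-4.32 ± 0.79) and EIF5AL1 (-2.25 ± 0.44), pseudogenes or close copies that share reads with their parent genes, so their values are uncertain. The smallest adjusted p by limma was 0.370. At an unadjusted p under 0.05 there were 1898 genes, 995 higher and 903 lower, against 710 expected by chance. The count ran from 719 (without Scr2 replicate 4) to 3928 (without Scr2 replicate 2) with 1 library left out and was 509 without Scr2 replicates 1 and 4. Overall 3.01% of genes had groups that did not overlap, against 1.59% by chance.

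Camera called 16 of 33 lists, 10 higher and 6 lower in the libraries labelled Myc2. Inflammatory and NF-kB targets rose by a median of 0.99 (19 of 20 members above 0, adjusted p = 2.29e-10, and adjusted p = 0.241 with an estimated correlation). In that list TNFAIP3 was higher by 2.64 ± 0.66 and BIRC3 by 1.62 ± 0.45, and 11 members passed when adjusted over the list alone. The hypoxic MES-like 2 list rose by 0.50 (44 of 49 members above 0, adjusted p = 2.03e-08), with EPAS1, a hypoxia-inducible factor, at 1.20 ± 0.27 and the glucose transporter SLC2A3 at 1.55 ± 0.38. The mesenchymal subtype list rose by 0.29 (47 of 62 members above 0, adjusted p = 0.000137) and the mesenchymal regulators by 0.56 (18 of 20, adjusted p = 1.19e-07), with STAT3 at 0.59 ± 0.17, SNAI2 at 0.89 ± 0.22 and BHLHE40 at 1.36 ± 0.38. Within the mesenchymal subtype list IL1R1 was higher by 0.94 ± 0.25 and LGALS1, which encodes galectin-1, lower, at -0.82 ± 0.21. With an estimated correlation these 3 lists had adjusted p = 0.241, and fry gave the mesenchymal subtype list adjusted p = 0.0455. Glycolysis rose by 0.46 (adjusted p = 0.000168), with hexokinase HK2 at 1.88 ± 0.44, and hypoxia core by 0.51 (adjusted p = 0.0140), with NDRG1 at 2.47 ± 0.74. Glycolysis and hypoxia had adjusted p = 0.473 and 0.534 with an estimated correlation. Extracellular matrix (0.36, adjusted p = 0.000395), unfolded protein response (0.35, adjusted p = 0.00120), angiogenic factors (0.66, adjusted p = 0.00438) and the MYC network (0.33, adjusted p = 0.0249, with MNT at 1.14 ± 0.36 and MXI1 at 1.45 ± 0.47) also rose. Their adjusted p with an estimated correlation were 0.473, 0.389, 0.241 and 0.241. The matrix and MYC network calls ended without Scr2 replicates 1 and 4, at medians of 0.0766 (adjusted p = 0.313) and 0.12 (adjusted p = 0.0984). Over the alternative processing settings the lowest MNT difference was 0.40. The hypoxia, unfolded protein, angiogenic and MYC network calls ended without Scr2 replicate 2, and the hypoxia call also without Scr2 replicate 3.

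Ribosomal protein genes fell by a median of 0.38 on the log2 scale, with 0 of 68 members above 0 (adjusted p = 2.29e-10), and oxidative phosphorylation genes fell by 0.41, with 39 of 41 below 0 (adjusted p = 1.13e-07). RPS27 differed by -1.03 ± 0.32, RPSA by -0.67 ± 0.23 and NDUFA9 by -0.59 ± 0.20. Ribosomal and respiratory lists both had adjusted p = 0.484 with an estimated correlation. Scr2 replicates 1 and 4, which stood apart on the first component, had the highest ribosomal scores of the 9 libraries, at 9.61 and 9.92 against 8.57 to 9.12 in the others. Cell cycle genes fell, G2/M by 0.28 (47 of 54 members below 0, adjusted p = 1.13e-07) and G1/S by 0.32 (35 of 42, adjusted p = 2.04e-05), with FAM64A at -0.81 ± 0.19, CDC25C at -0.99 ± 0.27 and BIRC5 at -0.68 ± 0.20. MYC targets (Hallmark V2) fell by 0.21 (43 of 56 below 0, adjusted p = 0.00203), with BYSL at -0.67 ± 0.23, although MYC was higher in the same libraries, and nucleotide synthesis genes by 0.16 (adjusted p = 0.0370). Cell cycle and MYC target lists had adjusted p = 0.473 with an estimated correlation and the nucleotide list adjusted p = 0.484. The proneural subtype list had a median of -0.03 (11 of 22 members above 0, adjusted p = 0.852), and MES-like 1 of 0.13 (adjusted p = 0.0860). Of other panel genes, CD44 differed by 0.42 ± 0.25, MET by 0.41 ± 0.20, FN1 by 0.22 ± 0.44, VIM by 0.13 ± 0.18, TIMP1 by -0.25 ± 0.21, NCAM1 by 0.17 ± 0.47, PDGFRA by -0.53 ± 0.70 and BCAN by -1.03 ± 0.51. Without Scr2 replicate 4 the difference was 0.16 for CD44, 0.24 for MET, 0.00981 for VIM and -0.13 for TIMP1, and without Myc2 replicate 3 it was -0.18 for PDGFRA. The host cell type lists had adjusted p from 0.228 to 0.965. The mesenchymal subtype score was 7.10 ± 0.08 (SD, n = 5) in Myc2 and 6.72 ± 0.11 (SD, n = 4) in Scr2, with every Myc2 library above every Scr2 library (exact permutation p = 0.00794, the smallest this design allows, and 0.0873 after adjustment over the 33 lists). Without Scr2 replicates 1 and 4, 14 lists passed, the ribosomal and oxidative phosphorylation lists turned to medians of 0.06 (adjusted p = 0.0988) and 0.0428 (adjusted p = 0.672), and the nucleotide call ended (adjusted p = 0.108). The medians of the mesenchymal subtype and regulators were then 0.17 and 0.34 and that of MYC targets -0.12, all still called, while inflammatory targets stood at 1.58 and G2/M genes at -0.54. The G2/M median was -0.15 without Scr2 replicate 2 alone. The nucleotide call also ended without Myc2 replicate 1, Myc2 replicate 2, Scr2 replicate 3 or Scr2 replicate 4 alone. Genes called were 9 without Myc2 replicate 3, 2 without Scr2 replicate 3 and 1 without Scr2 replicate 2.

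**Figure D3:**
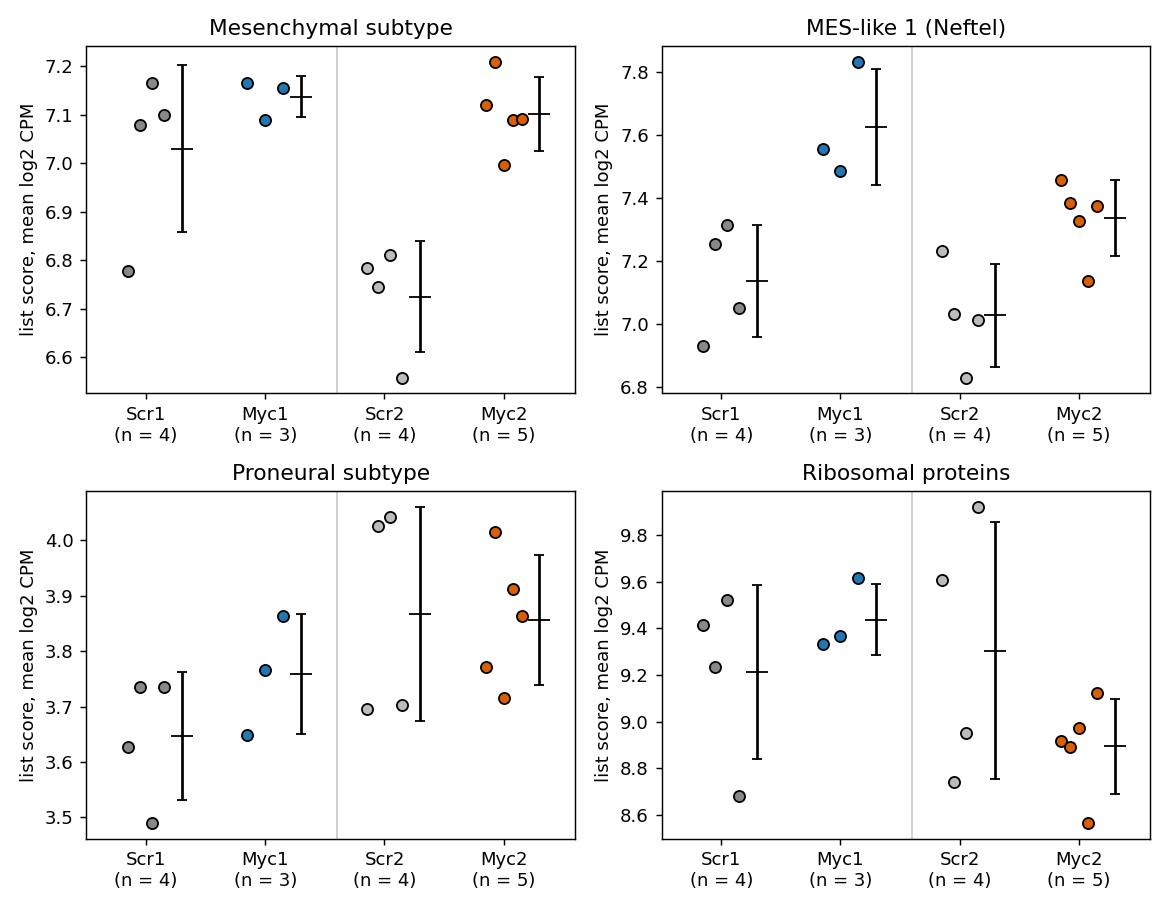
Scores of 4 lists (mean log2 CPM of members) in each tumour, by group. Points are tumours and the bar with whiskers beside them is the mean ± SD; mesenchymal subtype scores of the libraries labelled Myc2 (6.996 to 7.21) lie above those of Scr2 (6.56 to 6.81), the proneural scores overlap in both experiments, and Scr2 holds 2 libraries with ribosomal scores above 9.5.

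Set side by side, the 2 experiments had 0 genes past the adjusted threshold in their mean and no correlation of fold changes beyond that of rearranged labels. The siRNA 2 part of each mean follows the labels, which MYC goes against, and its sign would turn if the Myc2 and Scr2 labels had been exchanged. In the mean of both effects, CHI3L1 was higher by 2.30 ± 0.45 log2 units, C1S by 1.51 ± 0.32, C1R by 1.17 ± 0.27, CFB by 0.91 ± 0.22, APOE by 2.06 ± 0.46, IL1R1, the interleukin 1 receptor, by 1.11 ± 0.23, NAMPT by 0.91 ± 0.20, CEBPB by 0.73 ± 0.16 and the secreted kinase FAM20C by 1.16 ± 0.24. FAM46A (0.94 ± 0.18), RND3 (1.00 ± 0.21), STC2 (3.20 ± 0.74) and IL32 (2.32 ± 0.51) were among the genes with the smallest p, and LOX (1.07 ± 0.27), TNFAIP3 (1.61 ± 0.44), ICAM1 (2.10 ± 0.62) and MXI1 (1.27 ± 0.34) among the list members. Over the alternative processing settings the lowest values in the mean were 0.86 for IL32, 1.74 for STC2 and 0.94 for ICAM1. The macrophage receptor gene MSR1 differed by -1.41 ± 0.43. Limma called 0 of 14891 genes in the mean (smallest adjusted p = 0.322, 1181 genes at an unadjusted p under 0.05 against 745 by chance, and 709 without Scr2 replicate 4 to 1815 without Scr2 replicate 2) and 0 for the difference between siRNAs (smallest adjusted p = 0.532, 1301 genes unadjusted, and 583 to 2937 without the same libraries). Across the 13656 genes tested in both, the fold changes correlated at Pearson r = -0.00854 and Spearman rho = -0.102; genes are not independent replicates, and 0.967 of the 4410 label arrangements gave an r as far from 0. Without Scr2 replicates 1 and 4, r was 0.240. Of genes at an unadjusted p under 0.05 in each, 44 were higher in both, against 17.5 for independent lists (9 of 100 splits of the samples gave as many), and 9 were lower in both, against 13.8. In opposite directions there were 7 and 5, against 16.9 and 14.2.

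In the mean of both siRNAs camera called 19 of 32 lists, 13 higher and 6 lower, but 0 with an estimated correlation. Without Scr2 replicates 1 and 4 it called 13 higher and 2 lower: ribosomal proteins turned from -0.10 to 0.14 (adjusted p = 4.23e-06) and oxidative phosphorylation from -0.12 to 0.11 (adjusted p = 0.0150), and the extracellular matrix and astrocyte calls ended (adjusted p = 0.102 and 0.0967). With all libraries the astrocyte markers, a host list, rose by 0.48 (adjusted p = 0.00806, and adjusted p = 0.187 with an estimated correlation). The mesenchymal subtype list rose by a median of 0.16 (41 of 62 members above 0, adjusted p = 4.99e-05), MES-like 1 by 0.19 (31 of 47, adjusted p = 4.43e-05) and MES-like 2 by 0.35 (42 of 49, adjusted p = 5.57e-11). With an estimated correlation each of the 3 had adjusted p = 0.0747, and without Scr2 replicates 1 and 4 the mesenchymal subtype median was 0.0761 (adjusted p = 0.000212). Inflammatory targets rose by 0.76 (19 of 21 members above 0, adjusted p = 4.02e-11, and adjusted p = 0.1003 with an estimated correlation). G1/S genes fell by 0.23 (34 of 42 below 0, adjusted p = 5.10e-05) and MYC targets by 0.13 (39 of 56, adjusted p = 0.00744). G1/S and MYC target lists had adjusted p = 0.473 and 0.428 with an estimated correlation, and the MYC target call ended without Scr2 replicate 4 (adjusted p = 0.0610). With 1 library left out the G1/S median ran from -0.31 (without Scr1 replicate 3) to -0.13 (without Scr1 replicate 1), and camera still called it. The proneural subtype list had a median of 0.06 (adjusted p = 0.643). The effects of the siRNAs differed by camera for 10 lists, with ribosomal proteins (median difference 0.62, adjusted p = 1.72e-15) and oxidative phosphorylation (0.60, adjusted p = 2.47e-09) higher with siRNA 1 and mesenchymal regulators (-0.43, adjusted p = 0.000138) higher with siRNA 2, as labelled. With an estimated correlation these had adjusted p = 0.672, 0.672 and 0.414. Without Scr2 replicates 1 and 4 the ribosomal and respiratory differences shrank to 0.18 (adjusted p = 0.000788) and 0.19 (adjusted p = 0.00625). Without Scr1 replicate 4 the siRNA 1 medians themselves were 0.0436 and 0.0853.

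**Figure D4:**
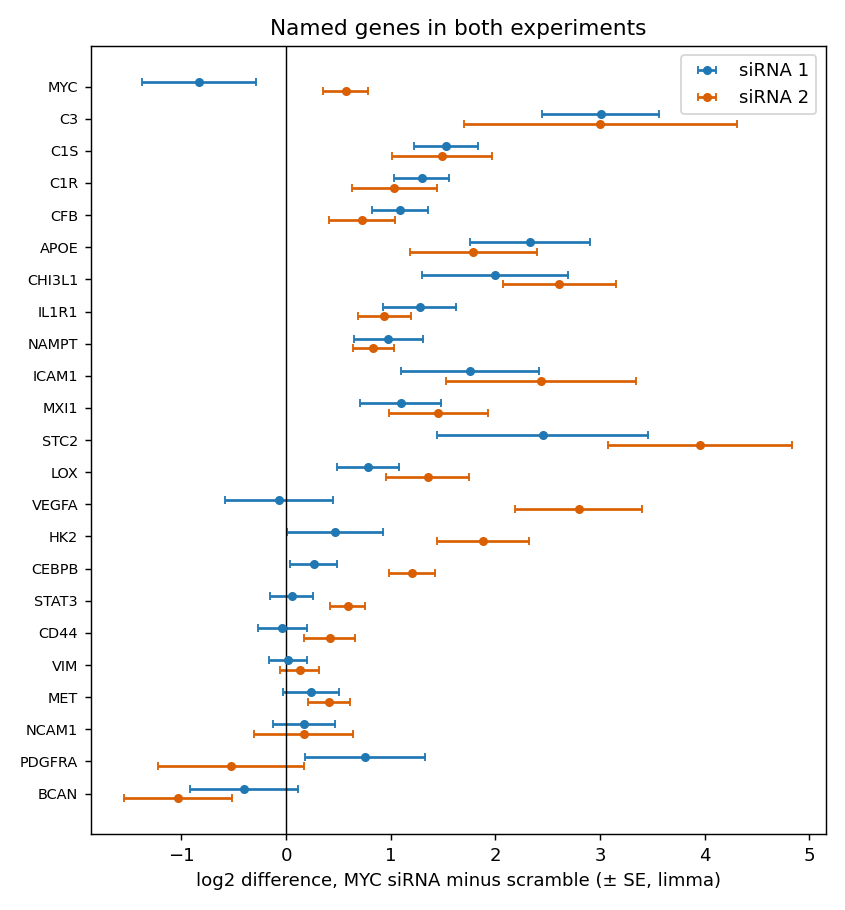
Log2 difference (MYC siRNA minus scramble, ± SE from limma) of named genes in both experiments. Complement genes, APOE, CHI3L1 and IL1R1 lie above 0 in both, MYC lies at -0.83 with siRNA 1 and 0.57 with siRNA 2, and no gene shown passed the adjusted threshold.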

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

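The tests on host markers, on the libraries that stood apart and on animal numbers were chosen only after the results were seen, and those on other splits of the samples, transcript length and GC content before.

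In several list scores and genes, 1 library lay far from the rest of its group. Among 233 groups of values tested 15 were set off in this way, against 11.65 expected by chance. Myc1, with n = 3, was too small for this test and was not among them. In Scr1 replicate 4 the NPC-like score was 4.63 (others 4.36 to 4.39) and the MYC network score 5.55 (others 5.19 to 5.23). In Scr1 replicate 2, FABP4 was at 2.63 log2 CPM (others 1.95 to 2.06), CHI3L1 at 6.80 (others 5.74 to 5.85) and NAMPT at 7.21 (others 6.10 to 6.25). Myc2 replicate 3 had the lowest AC-like score, 5.14 (others 5.503 to 5.63), the lowest extracellular matrix score, 6.56 (others 7.36 to 7.52), and the lowest astrocyte score, 3.11 (others 3.75 to 4.00). Myc2 replicate 1 had a MYC-activated score of 6.45 (others 6.62 to 6.68) and a MYC-repressed score of 6.61 (others 6.81 to 6.89). Scr2 replicate 2 had a G2/M score of 7.45 (others 6.81 to 6.91) and ATP5EP2 at 1.38 log2 CPM (others 1.99 to 2.10). Scr2 replicate 1 had an inflammatory score of 4.14 (others 2.37 to 2.65) and BHLHE40 at 6.51 (others 5.75 to 5.87), and Scr2 replicate 3 had SNAI2 at 5.33 (others 5.86 to 5.89).

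The effects of the siRNAs differed by camera, with siRNA 1 above siRNA 2 for ribosomal proteins (adjusted p = 1.72e-15), oxidative phosphorylation (adjusted p = 2.47e-09), G2/M genes (adjusted p = 0.00428) and the NPC-like list (adjusted p = 0.0461). As labelled, siRNA 2 lay above siRNA 1 for mesenchymal regulators (adjusted p = 0.000138), inflammatory targets (adjusted p = 0.00208), glycolysis (adjusted p = 0.00526), MES-like 2 (adjusted p = 0.0295), the MYC network (adjusted p = 0.0305) and the mesenchymal subtype (adjusted p = 0.0305). With an estimated correlation 0 lists differed (smallest adjusted p = 0.414). With 1 of the 16 libraries left out, the NPC-like call was kept in 8 settings, MES-like 2 in 10, and G2/M, the mesenchymal subtype and the MYC network in 12 each, and the G2/M median was -0.0526 without Scr1 replicate 3. This order follows the Myc2 and Scr2 labels. Were they exchanged, the difference would by construction be that of the mean as labelled, with siRNA 1 above siRNA 2 for mesenchymal regulators (adjusted p = 4.17e-05) and inflammatory targets (adjusted p = 4.02e-11). With an estimated correlation these had adjusted p = 0.147 and 0.1003.

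Chance arrangement of the samples could not be excluded for the counts of genes at an unadjusted p or for the counts of lists. For genes past the adjusted threshold the test decides nothing, because a real count of 0 is reached by every split by construction (35 of 35 for siRNA 1 and 100 of 100 drawn for siRNA 2, for the mean and for the difference, with up to 5, 12, 78 and 0 genes in another split). For genes at an unadjusted p under 0.05, 19 of 35 splits reached the 485 genes of siRNA 1 (highest other 1809), 11 of 100 the 1898 of siRNA 2 (highest other 4189), 19 of 100 the 1181 of the mean (highest other 3340) and 14 of 100 the 1301 of the difference (highest other 3343). The 10 siRNA 2 splits with the most genes all kept Scr2 replicates 1 and 4 on the same side, as 48 of the 100 drawn did. The split with 4189 genes was the real one with Myc2 replicate 5 and Scr2 replicate 2 exchanged. Since the real split also keeps Scr2 replicates 1 and 4 together, this does not tell a structure of the samples from treatment. For lists called by camera at its preset correlation, 12 of 35 splits reached the 11 of siRNA 1 (highest other 16), 5 of 100 the 16 of siRNA 2 (highest other 19) and 25 of 100 the 10 of the difference (highest other 19). The other splits called a median of 6 lists for siRNA 1 and 7 for siRNA 2. The 19 lists of the mean were reached by 1 of 100 splits, the real one (highest other 18), a margin of 1 list at camera's preset correlation. It was the only count tested in this way with a share under 0.05. That share was not corrected for the number of counts tested, so it does not exclude chance. With the Myc2 and Scr2 labels exchanged the mean becomes the difference, whose 10 lists were reached by 25 of 100 splits, so the low share holds only if the labels are right. With an estimated correlation the mean had 0 lists.

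The first pattern is the set of 44 genes higher with both siRNAs, which holds C3, C1R, C1S, C4A, C4B, CFB, CHI3L1, APOE, ICAM1 and NFKBIA (C4A and C4B are near-identical copies, and this set was named after its values were seen). Reads from host brain cells would raise host markers by about as much as these genes, whose median was 1.18 with siRNA 1 and 1.17 with siRNA 2. The host markers tested had a median of 0.00940 (SD 0.79, 43 genes) with siRNA 1 and 0.03 (SD 0.75, 52 genes) with siRNA 2. The 44 genes were picked for being higher in both experiments, so their median was bound to lie above that of unselected markers. The comparison therefore does not decide on host cells, and shows only that host markers as a whole hardly rose. Astrocyte markers were higher with siRNA 1 (0.53) and as a list in the mean (0.48, adjusted p = 0.00806, and adjusted p = 0.187 with an estimated correlation). With siRNA 2 their median was 0.43, but the list was not called (camera adjusted p = 0.228). Without the Scr2 libraries that stood apart, the astrocyte median was -0.0639 with siRNA 2 (camera adjusted p = 0.838). In the mean it was then 0.24 (camera adjusted p = 0.0967). Reads from host cells, astrocytes among them, stay open, but the siRNA 2 rise of astrocyte markers rests on those libraries. Chance stays open, since 9 of 100 splits gave 44 or more shared higher genes (highest other 188). A shared response of tumour cells to MYC siRNA is an untested alternative that may also account for it.

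The second pattern is the lower ribosomal protein and oxidative phosphorylation genes with siRNA 2. Their 109 members had a median log2 difference of -0.40 (SD 0.19), and without Scr2 replicates 1 and 4 it was 0.0481 (SD 0.17), so the pattern rests on those 2 libraries. Against 20 genes of matched transcript length the median was -0.34 (SD 0.22) and against genes of matched GC content -0.35 (SD 0.22). Most of the -0.40 thus remained after matching for either property. Whether either contributes in part stays open, because the bound set in advance counted the SD between members, which spans it. A candidate explanation is a difference in those libraries' preparation or RNA, and the labels name no batch that would test it.

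The third pattern is higher MYC, mesenchymal and hypoxia transcripts with siRNA 2. Without Scr2 replicates 1 and 4 the mesenchymal subtype difference was 0.32 against 0.38 with all libraries (larger group SD 0.11), which argues against those libraries as its whole source, but the median of the members was 0.17 against 0.29 (for both siRNAs 0.0761 against 0.16), so they may account for part of it. The hypoxia difference was 0.77 without them against 0.61 with them, so leaving them out did not shrink it. Its size stays uncertain, with a larger group SD of 0.54 and the lowest Myc2 score (7.11) below the highest remaining Scr2 score (7.44). The MYC difference was 0.40 without them against 0.57 with them, and with a larger group SD of 0.37 that value does not decide. The animals' numbers also differ: those of Scr2 run from 922 to 929 and those of Myc2 from 728 to 921, 1 of them close to the Scr2 numbers, and what the numbers mean is not given. The mesenchymal score of that 1 animal, Myc2 replicate 5, lay 0.28 above the highest Scr2 score, but a single library excludes nothing, so a cohort difference, an exchange of the Myc2 and Scr2 labels and the treatment cannot be told apart.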

How the results depend on the processing

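No paired analysis was possible because the labels carry no replicate numbers shared between groups. The planned quantile normalization could not be tried, since the values already were quantile-normalized, and a median-of-ratios shift chosen after seeing the data stood in for it (largest shift of a sample 0.10 log2 units). A gene result counted as the same when its sign and its side of the adjusted threshold were unchanged, whatever its size. By that rule 1836 of 1872 settings over 100 gene results were the same. Another 12 were stronger (past the threshold) and 24 reversed, the last in 7 genes. Since no gene passed with all libraries and many were chosen for a small p, this count does not measure how stable the sizes were. PMS2P10 with siRNA 2 reached -1.52 against -4.32, and PDGFRA with siRNA 1 reached 0.27 against 0.75, both counted as the same.

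Genes called by limma for siRNA 1 moved to 1 with a filter of CPM at least 10 and ran from 0 (without Myc1 replicate 3) to 2 (without Myc1 replicate 1). For siRNA 2 they moved to 2 without Scr2 replicates 1 and 4 and ran from 0 (without Myc2 replicate 1) to 9 (without Myc2 replicate 3), and for both siRNAs from 0 (without Myc1 replicate 2) to 1 (without Myc1 replicate 1). Lists called moved to 0 with an estimated correlation in all 4 comparisons, with fry to 0 for siRNA 1, both siRNAs and the difference and to 1 for siRNA 2, and with exact permutation of list scores to 0 for siRNA 1 and 0 for siRNA 2. They ran from 5 (without Myc1 replicate 3) to 13 (without Myc1 replicate 1) for siRNA 1 and from 4 (without Myc1 replicate 2) to 13 (without Scr2 replicate 1) for the difference. MYC with siRNA 2 was weaker without Scr2 replicates 1 and 4, at 0.40 (exact permutation p = 0.238), and ran from 0.41 (without Scr2 replicate 4) to 0.70 (without Scr2 replicate 3). The correlation of fold changes moved to 0.240 without Scr2 replicates 1 and 4 (jackknife SE 0.221).

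Adjusted p of lists changed as follows. MES-like 1 with siRNA 1 was weaker with an estimated correlation (0.395), fry (0.521) and permutation (0.457). With siRNA 2 it was stronger without Scr2 replicates 1 and 4 (0.000405) and ran from 0.01001 (without Scr2 replicate 1) to 0.299 (without Scr2 replicate 2). For both siRNAs it was weaker with an estimated correlation (0.0747) and fry (0.0599). The mesenchymal subtype with siRNA 1 ran from 0.0411 (without Scr1 replicate 4) to 0.920 (without Scr1 replicate 1). With siRNA 2 it was weaker with an estimated correlation (0.241) and permutation (0.0873), and for both siRNAs with an estimated correlation (0.0747) and fry (0.0599). MYC targets with siRNA 1 ran from 0.220 (without Scr1 replicate 2) to 0.983 (without Myc1 replicate 2). With siRNA 2 they were weaker with an estimated correlation (0.473), fry (0.281) and permutation (0.262). For both siRNAs they were weaker without Scr2 replicates 1 and 4 (0.0723), with an estimated correlation (0.428) and with fry (0.259), and ran from 0.00164 (without Scr2 replicate 2) to 0.0610 (without Scr2 replicate 4). The proneural subtype for both siRNAs reversed without Scr2 replicates 1 and 4 (0.798), and with siRNA 2 it ran from 0.401 (without Scr2 replicate 4) to 0.992 (without Scr2 replicate 2, reversed); the cause was not tested.

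Small gene differences also reversed, and the cause was not tested. With siRNA 1, VIM was -0.0139 with array weights, CD44 0.0884 and FN1 -0.0409 with the host marker covariate. With siRNA 2, FN1 was -0.24 and PDGFRA 0.11 with array weights, and FN1 was -0.57 and NCAM1 -0.24 without Scr2 replicates 1 and 4. With 1 library left out, siRNA 1 values ran from -0.32 to 0.16 for CD44, -0.0759 to 0.14 for VIM, -0.13 to 0.21 for FN1, -0.0120 to 0.36 for TIMP1 and -0.0565 to 0.14 for STAT3. In siRNA 2 they ran from -0.22 to 0.57 for FN1 and -0.0887 to 0.54 for NCAM1.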

Other observations

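Among lists the report gives only in passing, interferon-stimulated genes had a median log2 difference of 0.02 with siRNA 1 (20 of 37 members above 0, adjusted p = 0.760) and 0.12 with siRNA 2 (22 of 37, adjusted p = 0.196, and 0.19 with adjusted p = 0.00103 without Scr2 replicates 1 and 4). Genes of the p53 response had medians of 0.07 (adjusted p = 0.830) and -0.08 (adjusted p = 0.687), and glioma stem cell genes -0.02 (adjusted p = 0.922) and 0.01 (adjusted p = 0.965), by limma's camera. The OPC-like list, the oligodendrocyte-progenitor-like state, had medians of 0.04 (adjusted p = 0.587) and 0.01 (adjusted p = 0.965), and the classic MYC-repressed list 0.14 (adjusted p = 0.587) and 0.19 (adjusted p = 0.170). With siRNA 2 the MYC-repressed list was called without Scr2 replicates 1 and 4 (0.31, adjusted p = 0.0220), and in the mean of both siRNAs it was called with all libraries (0.0767, adjusted p = 0.0422, and adjusted p = 0.187 with an estimated correlation), a call that 9 of the 16 settings with 1 library left out kept.

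Among the 9 genes lower with both siRNAs, GLI1, a Hedgehog pathway transcription factor, differed by -1.28 and -1.03, PPARG, a regulator of fat cell genes, by -0.70 and -1.25, and its target FABP4 by -1.48 and -1.65 log2 units. These were chosen after their values were seen, none passed the adjusted threshold in either experiment, and 9 is below the 13.8 that independent lists would share.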
